A study of Homo sapiens with 2 samples.

How the data were processed

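N6-methyladenosine (m6A) was mapped by antibody capture in HCCLM3, a human hepatocellular carcinoma cell line with high metastatic capacity. Per the labels, the cells were of wild-type genotype, and RNA was prepared with a Magna RIP kit and a SMARTer stranded total RNA kit for low input amounts. There was 1 immunoprecipitated (RIP) library and 1 input library, each in a group of its own, and no replicate of either.

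Reads were aligned with HISAT2 and peaks called with MACS2 on hg38, per the submitters' processing notes, which give no versions. The caller's settings, its threshold and any removal of duplicate reads are not given in the sources used here. The authors deposited 1 annotated peak table, in which each peak has a position, a summit, a fold over input, a p-value, a q-value, a region label and a gene. The fold is a linear ratio of RIP to input at the summit, per the file headers. The headers of the p-value and q-value columns of the deposited table were damaged. Their values were taken as −log10 of the p-value and −log10 of the q-value from the values themselves: 99.99% of the table's scores are 10 times the first of these columns rounded down, and the lowest value, 1.30, equals a p-value of 0.05. Fold, −log10 p-value and −log10 q-value are values that the authors' peak caller computed for each peak from RIP and input before deposit. They are the authors' values and were used within this list only, to describe, rank and filter peaks, to recover fragment numbers and to compare gene lists by fold. Peaks are numbered up to 39824, and 39801 were used here, so 23 numbers are not among the peaks used here.

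The deposited table gives each peak the gene with the nearest transcript start, whether or not the peak lies in that gene. Gene identifiers matched a RefSeq gene table of GRCh38.p14, whose main chromosomes are those of hg38, for 39756 peaks (99.9%), and 398 older symbols were updated. A further assignment was made here, to the gene whose body holds the summit, taking in order the gene of the deposited exon or intron label, the deposited gene if it holds the summit, or the lone protein-coding gene there. Region labels were kept as deposited; a promoter label reaches 3 kb from a transcript start and takes precedence over exon, intron and UTR labels, so a promoter peak can lie inside a transcript. The table carries no strand for a peak, so overlapping and antisense genes cannot be told apart. The replication-dependent histone genes and other near-identical copies are uncertain for the same kind of reason, since reads may be shared between copies.

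The number of RIP fragments and the local input level at each summit were recovered from fold and p-value. The fold was modelled as the scaled RIP fragments plus a pseudocount of 1 over the input level plus 1, and the p-value as a Poisson tail. With a scaling factor of 0.642, whole numbers of fragments met both values for 100% of the 39801 peaks within 0.001 on the −log10 p scale, and for 98.2% only 1 whole number did. Without scaling, 1.31% of peaks were met. On 2000 simulated peaks the fragments were recovered for 100%. The scaling factor makes the RIP library 1.56 times the size of the input. Total depth is not stated; under an assumed effective genome of 2.7 Gb, the lowest input level would correspond to 2.24 M input and 3.50 M RIP fragments. Intervals on a fold are exact 95% Poisson intervals on the RIP fragments with the input level held fixed, and intervals on a share are 95% Wilson intervals. Both cover counting error only, and fragments without molecular identifiers are not independent molecules.

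No test between conditions was possible, and no p-value was computed across peaks or genes. Before the data were examined, 26 gene lists were fixed, together with the rule for named genes: the 10 genes of highest fold and the 10 of highest −log10 p by their best peak outside intergenic sequence, the 5 genes with most peaks, up to 4 genes of highest fold and up to 4 without a peak per list, and in every case CRTC2, YTHDF2, the other m6A writers, erasers and readers, MYC, EGFR and MALAT1. For each list, the share of genes with a peak outside intergenic sequence was placed among 10000 random lists of the same size, matched on biotype and on 10 classes of gene length. The plan was to match on exonic length; no transcript models were used here, so the genomic span of the gene was used in its place. The median over a list of each gene's highest fold was placed among 10000 random lists matched on the number of peaks per gene in 6 classes. Percentiles below 2.5 or above 97.5 are pointed out; they describe these libraries and are not p-values. Lists were not matched on expression, so a share also depends on how much RNA of the genes was present. On simulated lists of 40 genes from 20056 protein-coding genes, 93% of 100 lists with added peaks were found above the 97.5th percentile, and 1% of 100 lists without added peaks fell outside the range. The added peaks were a large rise in the share, so this does not cover smaller differences or shorter lists. The oxidative phosphorylation list had 63 genes after matching, since NDUFA4 was not matched.

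The alternatives were stricter q-value and fold thresholds, merging of close peaks, narrow peaks, peak bases in place of peaks, exonic and UTR peaks only, no matching, and the median in place of the highest fold. Alternatives chosen after seeing the data were a q-value under 0.05, at least 10 RIP fragments, assignment by gene body, and matching on input level. The DRACH motif share, the density of peaks at stop codons and a second annotation of regions were not run, as no genome sequence or transcript models were used here. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.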

Results

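Transcripts carrying m6A, the commonest internal modification of mRNA, were surveyed in wild-type HCCLM3 cells by comparing 1 m6A-RIP library with 1 input library. The series concerns CRTC2, a coactivator of the transcription factor CREB, and YTHDF2, a cytoplasmic protein that binds m6A, in liver cancer cells and their resistance to lenvatinib, an inhibitor of receptor tyrosine kinases. The comparison addresses which transcripts, and which parts of them, were recovered by the m6A antibody above input. There were no replicates, so every value describes these libraries, and differences between genes or regions have no replicate check. Positions are on hg38.

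The deposited list held 39801 peaks with a median width of 371 bp (quartiles 301 to 534). The nearest-start rule of the deposited table assigned the peaks outside intergenic sequence to 12078 genes. By the gene body that held the summit they fell in 10677 genes, of which 9347 were protein-coding, or 46.6% of 20056 protein-coding genes. The median fold over input was 3.33 (quartiles 2.35 to 4.61), with a range from 1.15 to 28.5. A median of 9 RIP fragments lay under a summit (quartiles 4 to 26), and 8528 peaks (21.4%) rested on at most 3 fragments. The caller's q-value was 1 for 10323 peaks (25.9%), under 0.05 for 19438 (48.8%) and under 1e-5 for 10267 (25.8%).

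Introns held the largest share of the list, with 15069 peaks (37.9%, interval 37.4 to 38.3). Distal intergenic sequence held 6978 (17.5%, 17.2 to 17.9), exons outside UTRs 5991 (15.1%, 14.7 to 15.4) and 3' UTRs 5749 (14.4%, 14.1 to 14.8). Promoter labels covered 5556 peaks (14%), while 5' UTRs held 441 (1.11%). The order depended on the strength of the peaks. Among peaks with a q-value under 1e-5, 3' UTRs held 30.0% (29.1 to 30.9), exons 25.1% (24.3 to 26.0) and introns 16.4% (15.7 to 17.1). Exons and UTRs together went from 30.6% of all peaks to 46.3% at a q-value under 0.05 and 57.0% at a q-value under 1e-5.

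**Figure D1:**
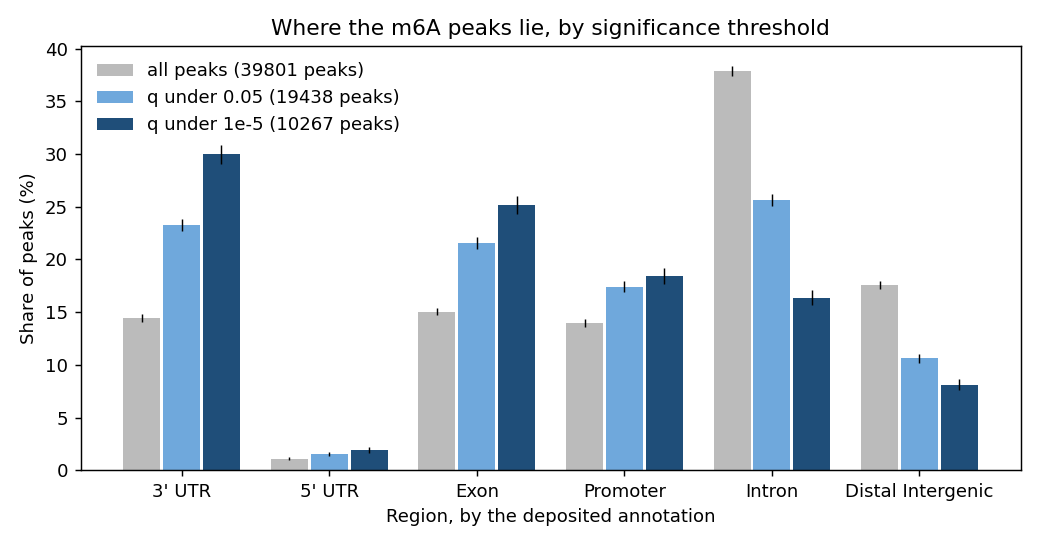
Share of peaks (%, vertical axis) in each region of the deposited annotation (horizontal axis) for all 39801 peaks, the 19438 with a q-value under 0.05 and the 10267 with a q-value under 1e-5; error bars are 95% Wilson intervals. The 3' UTR share is 14.4%, 23.3% and 30.0% in that order, and the intron share 37.9%, 25.6% and 16.4%.

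Fold over input also differed by region. The median was 4.12 in 3' UTRs (quartiles 2.99 to 5.86), 3.98 in 5' UTRs, 3.80 in exons, 3.45 at promoters, 2.90 in introns (2.35 to 4.03) and 2.86 in intergenic sequence. The depth behind these medians was unequal, with a median of 32 RIP fragments per 3' UTR peak against 6 per intron peak and 5 per intergenic peak. The median input level was 3.55 in 3' UTRs and 0.296 in introns. The pseudocount of 1 lowers the fold most where input is low, so these medians do not rank the regions by enrichment. In 3' UTRs 78.6% of peaks had a q-value under 0.05, against 33.1% in introns. The median in 3' UTRs was 1.42 times that in introns over all peaks, and 0.854 times among peaks with a q-value under 1e-5, so the direction turned with the threshold.

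The highest fold, 28.5 (interval 21.7 to 36.8, 56 RIP fragments), was in the 3' UTR of CREBRF, a regulator of the CREB3 family, on chromosome 5 from 173090564 to 173091588. NFIA, a nuclear factor I transcription factor, followed with a fold of 27.1 (20.4 to 35.3) in exon 2 of 11 on chromosome 1 from 61088154 to 61088837. A peak assigned to CEBPG lay in intron 9 of 14 of PEPD on chromosome 19 from 33422180 to 33423083, with a fold of 26.9 (20.4 to 34.9). Intron 2 of 5 of ENKUR on chromosome 10, from 25054273 to 25054806, held a fold of 25.5 (20.3 to 31.7). Exon 19 of 41 of ITSN2, an endocytic scaffold gene, held a fold of 23.5 (17.4 to 31.1) on chromosome 2 from 24275426 to 24275834. The other 5 of the top 10 were assigned to PARP12, PON1, EEPD1, DISC1-IT1 and VPS26C, with folds of 21.9 to 23.0. Of these, the PARP12 peak lay in an intron of TBXAS1, the PON1 peak in the 3' UTR of PPP1R9A and the DISC1-IT1 peak in an intron of TSNAX-DISC1.

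The smallest p-values favoured peaks with many fragments. The highest −log10 p, 81.1, belonged to a 3' UTR peak of ZNF865 on chromosome 19 from 55616531 to 55617292, which the deposited table assigned to ZNF784; its fold was 13.1 (11.2 to 15.3) on 162 RIP fragments. The peak assigned to QTMAN lay in the 3' UTR of ZEB2, a repressor of epithelial genes, on chromosome 2 from 144389099 to 144389851, with a fold of 15.7 (13.1 to 18.8). The cadherin gene CDH6 had a 3' UTR peak of fold 15 (12.5 to 18.0) on chromosome 5 from 31322839 to 31324060. Other genes of this group were PURA (fold 12.7), SDE2 (8.62), TSR3 (11), ZC3H13 (16.6), CYTH3 (14, in an exon of USP42) and ENKUR.

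The nearest-start rule often named a neighbour. Of 32533 peaks outside intergenic sequence on the main chromosomes, the assigned gene held the summit in 19966 (61.4%). The share was 46.8% for 3' UTR peaks, 58.3% for exon peaks and 81.6% for 5' UTR peaks. Both assignments named 8656 genes, while 3422 were named by nearest start alone and 2021 by gene body alone. The 5 genes assigned most peaks were ACO1 (68), RAB9BP1 (56), PARAIL (50), MIR3144 (45) and BRDTP1 (44), and nearly all of those peaks were intergenic. By gene body, the scaffold gene MAGI2 held 53 peaks, of which 46 were intronic and 21 had a q-value under 0.05. PDE4D, a cAMP phosphodiesterase gene, held 45, GRIP1 42, PLCB1 37 and EXOC6B 35.

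Genes of the m6A machinery carried peaks themselves. Of the 11 writer genes, 8 held a peak in their body, each with at least 1 at a q-value under 0.05. ZC3H13, a nuclear anchor of the methyltransferase complex, held 14 peaks, the strongest in exon 15 of 19 on chromosome 13 from 45967359 to 45967966 with a fold of 16.6 (13.7 to 19.8, 116 fragments). VIRMA, a scaffold of the complex, had a fold of 6.18 (4.61 to 8.13), the methyltransferase METTL16 5.82 (4.57 to 7.31) and METTL14 5.58 (3.56 to 8.39), all in 3' UTRs. CBLL1 reached 4.40 (3.77 to 5.11), RBM15 3.98 (3.35 to 4.71) and RBM15B 2.99 (2.55 to 3.49); 5 other peaks assigned to RBM15B lay in DCAF1. METTL3, the catalytic subunit, had 1 promoter peak on 8 fragments with a fold of 3.85 (2.02 to 6.98). WTAP, ZCCHC4 and METTL5 had no peak under either assignment.

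Of the 16 eraser and reader genes, 13 held a peak in their body, and 11 held one at a q-value under 0.05. IGF2BP1 and PRRC2A held none at that threshold. YTHDC1, the nuclear reader, had the highest fold, 13.7 (9.13 to 19.8), in exon 3 of 17 on chromosome 4 from 68336791 to 68337658. YTHDF2 held 3 peaks, all with a q-value under 0.05. They were a 3' UTR peak of fold 5.14 (3.75 to 6.88) on chromosome 1 from 28768967 to 28769325, a peak of fold 3.95 (3.33 to 4.65, 140 fragments) in exon 5 of 6 from 28742595 to 28744471, and an intron peak of fold 4.35 (2.49 to 7.22). The strongest peak assigned to YTHDF2, with a fold of 11, lay in GMEB1. Its paralogs YTHDF1 and YTHDF3 had highest folds of 4.96 (3.02 to 7.77) and 3.73 (2.76 to 4.95), and YTHDC2 4.80 (2.97 to 7.44). Among the insulin-like growth factor 2 mRNA-binding readers, IGF2BP3 reached 5.50 (4.34 to 6.89) and IGF2BP2 5.22 (3.63 to 7.31), both in 3' UTRs, while IGF2BP1 had 1 intron peak of fold 2.37 (1.62 to 3.37). The demethylase gene FTO held 12 peaks, 4 of them with a q-value under 0.05, and the strongest had a fold of 6.67 (4.83 to 8.99). ALKBH5, the other demethylase gene, had 1 peak of fold 2.18 (1.83 to 2.58). RBMX (3.80), HNRNPC (2.66) and PRRC2A (3.89, on 6 fragments of an alternative contig) had 1 peak each, and HNRNPA2B1, FMR1 and ELAVL1 had none by gene body; the 1 peak assigned to HNRNPA2B1, of fold 4.75, lay in NFE2L3.

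CRTC2 held 3 peaks with a q-value under 0.05, each assigned to its neighbour DENND4B in the deposited table. The strongest was in exon 8 of 14 on chromosome 1 from 153951867 to 153952584, with a fold of 3.69 (2.85 to 4.70) on 62 fragments, and the others had folds of 3.61 (2.60 to 4.88) and 2.51 (1.95 to 3.19). The proto-oncogene MYC had 1 peak, in its 3' UTR on chromosome 8 from 127740654 to 127741252, with a low fold of 2.0 (1.72 to 2.32) over a high input level of 55.0. EGFR, the epidermal growth factor receptor gene, held 11 peaks, 8 with a q-value under 0.05. Its strongest was in intron 1 of 15 on chromosome 7 from 55095560 to 55096192 with a fold of 12.4 (10.1 to 15.1). A 3' UTR peak from 55205399 to 55206816 had a fold of 8.11 (6.90 to 9.47) and was assigned to the antisense gene EGFR-AS1. The nuclear RNA MALAT1 had no peak in its body among the peaks used here.

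**Figure D2:**
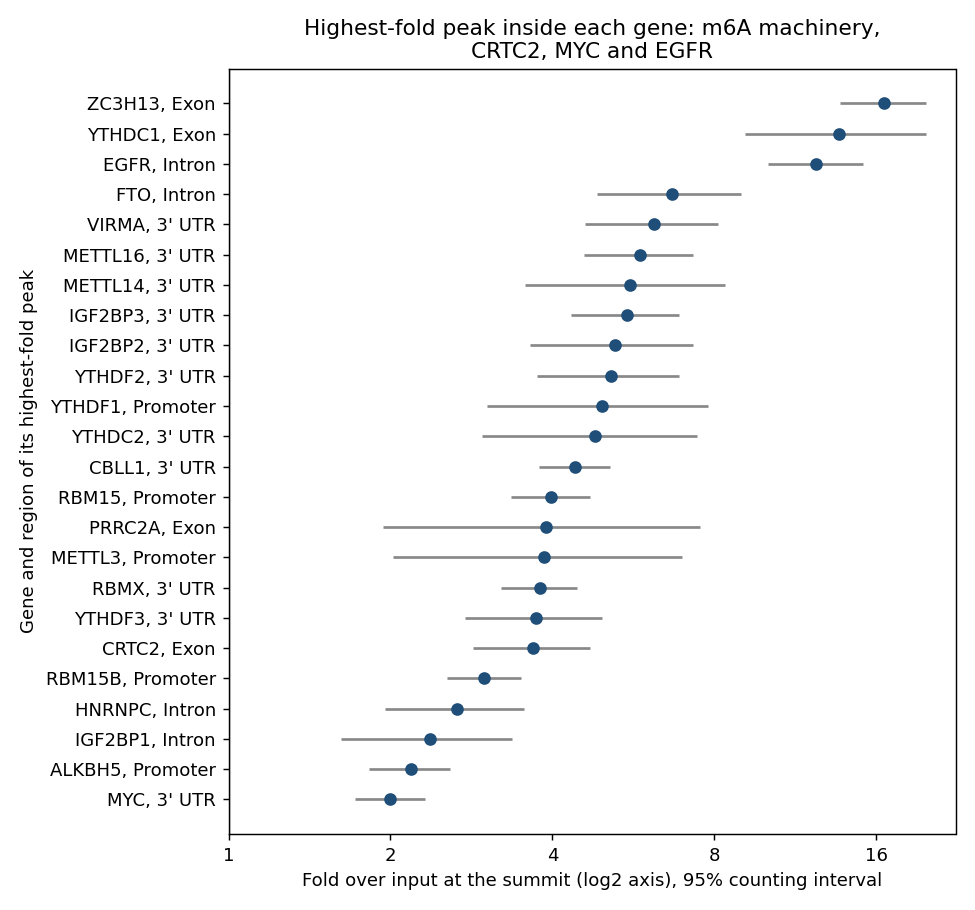
Fold over input at the summit (horizontal log2 axis) of the highest-fold peak inside each gene of the m6A machinery and inside CRTC2, MYC and EGFR; bars are 95% counting intervals from 1 RIP and 1 input library. ZC3H13 (16.6), YTHDC1 (13.7) and EGFR (12.4) stand highest, and ALKBH5 (2.18) and MYC (2.0) lowest.

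CREB coactivators and regulators were often peak-bearing, though by nearest start this did not hold for stricter sets of peaks. These lists were not matched on expression either. Of 19 CREB coactivators and regulators, 15 (78.9%) were assigned a peak, at percentile 97.8 of length-matched random lists (mean 56.1%), and 18 held one by gene body (percentile 99.9). PRKAR1A alone had none by gene body. The strongest peaks were in ATF1 (3' UTR, fold 12.4, 9.85 to 15.5), SIK3, a kinase that restrains CRTC proteins (3' UTR, 11.9, 8.60 to 16.1), CREB1 (3' UTR, 9.16, 6.21 to 13.1) and CRTC1 (exon, 8.84, 5.95 to 12.7). By nearest start the percentile was 86.1 at a q-value under 0.05 and 81.6 at a q-value under 1e-5. It was 89.3 at a fold of at least 4 and 71.2 with exonic and UTR peaks only. By gene body it was 99.99 at a q-value under 0.05. Of 18 classical CREB target genes, 10 were assigned a peak (55.6%, percentile 88.1) and 11 held one by gene body (percentile 97.3, but 98.7 without intron peaks). By nearest start at a q-value under 1e-5 their percentile was 27.2. NR4A1 reached a fold of 8.69 (5.55 to 13.1), whereas the gluconeogenic genes PCK1 and G6PC1, and PPARGC1A and FOS, had none under either assignment.

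The 10 receptor kinases that lenvatinib inhibits carried few peaks by gene body. By nearest start, 4 were assigned a peak (40%, percentile 21.1), but those of FGFR4, FGFR2 and FGFR3 lay in ZNF346, ATE1 and LETM1. By gene body only FLT1 held one, an intron peak on 3 fragments with a fold of 2.35 (1.12 to 5.32), and the list stood at percentile 0.09. The random lists were not matched on expression, so this share also depends on how much RNA of these genes was present. Of 44 EGFR, MAPK and PI3K genes, 27 were assigned a peak (61.4%, percentile 83.8) and 36 held one by gene body (81.8%, percentile 99.9). By nearest start the percentile was 71.6 at a q-value under 0.05 and 78.4 at a q-value under 1e-5. It was 73.2 at a fold of at least 4 and 24.1 with exonic and UTR peaks only. By gene body it was 99.99 without intron peaks. The call above the random range thus depended on the assignment. The 3' UTRs of PIK3CA, the catalytic subunit p110 alpha (14.2, 10.9 to 18.2), TSC1 (13.6, 10.5 to 17.5) and PDPK1 (9.72, 8.24 to 11.4) had the strongest peaks besides EGFR, and NRAS, MAP2K2, MAPK3 and AKT1 had none by gene body.

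Hippo and Wnt genes were also often peak-bearing. Of 29 Hippo genes, 24 were assigned a peak (82.8%, percentile 99.9) and 25 held one by gene body, with LATS2 (5' UTR, 16, 12.1 to 20.8) and STK3 (intron, 12.8, 9.35 to 17.1) the strongest. Both encode kinases of the core cascade. Of 38 Wnt genes, 24 were assigned a peak (63.2%, percentile 93.1) and 30 held one by gene body (78.9%, percentile 99.97). The receptor genes FZD7 (11.2, 8.45 to 14.7), FZD6 (10.8, 8.09 to 14.2) and LRP5 (9.86, 8.10 to 11.9) and the ubiquitin ligase gene RNF43 (11.2, 8.34 to 14.8) led this list. At a q-value under 1e-5 by nearest start, Hippo genes stood at percentile 96.3 and Wnt genes at 99.3. At a fold of at least 4 the percentiles were 96.4 and 87.7, and with exonic and UTR peaks only 93.0 and 47.1, in the same order.

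In the liver cancer lists, 23 of 35 driver genes were assigned a peak (65.7%, percentile 95.5) and 27 held one by gene body (percentile 99.7). ACVR2A (3' UTR, 11.7, 8.32 to 16.1) was among the strongest, while CCNE1, ALB and TSC2 had none by gene body. Hepatocyte markers lay within the random range, with 18 of 35 by nearest start (51.4%, percentile 84.8) and 15 by gene body (percentile 61.8). Within them, the regulator HNF4A (11.5, 8.54 to 15.1) and the lipoprotein gene APOB (8.53, 5.13 to 13.5) had strong peaks, and the secreted protein genes ALB, APOA1, APOA2 and APOC3 had none by gene body. Of 14 oncofetal and progenitor markers, only SOX9 (7.69, 5.82 to 9.99) and IGF2BP1 were assigned a peak (14.3%, percentile 0.35), and AFP, GPC3, EPCAM and KRT19 had none under either assignment. Immune cell markers (2 of 18, percentile 0.205) and endothelial and stromal markers (3 of 20, percentile 0.06) also stood low by nearest start, and the 3 lists stood at percentiles 1.19, 0.26 and 0.015 by gene body. By nearest start these calls ended at a q-value under 1e-5 (oncofetal 5.13, immune 11.8, endothelial and stromal 4.33), at a fold of at least 4 for oncofetal (2.73) and immune markers (8.54), and with exonic and UTR peaks only for immune markers (7.28). CSF1R and CD8A were the immune genes assigned a peak, in HMGXB3 and RMND5A, and RGS5, PECAM1 and LUM the endothelial or stromal ones. None of these lists was matched on expression.

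C2H2 zinc finger genes, chromatin regulators and immediate early factors held peaks more often than their random lists, which were not matched on expression. The C2H2 zinc finger list took every protein-coding gene with a symbol of ZNF plus a number, by symbol alone. Of these 509 genes, 337 (66.2%) were assigned a peak against a mean of 47.7% in random lists (range 43.4 to 51.7, percentile 100). By gene body, 365 held one. ZNF500 (15.7, 11.3 to 21.3), ZNF616 (15.5, 11.4 to 20.6) and ZNF518A (14.9, 11 to 19.8) were the strongest. Of 63 chromatin regulators, 50 were assigned a peak (79.4%, percentile 100) and 57 held one by gene body, led by the bromodomain gene BRD3 (13.1, 9.78 to 17.2), the histone methyltransferase gene NSD1 (12.6, 9.996 to 15.7) and the DNA demethylase gene TET3 (12.1, 8.02 to 17.6). Immediate early transcription factors, which respond to growth signals, had 18 of 24 genes assigned (75% against a random mean of 36.3%, percentile 99.99; 96.1 at a fold of at least 4), including NR4A1, HES1 (6.77, 5.55 to 8.18) and EGR1 (6.69, 5.62 to 7.91). Of 22 nuclear long non-coding RNAs, 9 were assigned a peak (40.9% against 9.47%, percentile 100), with TUG1 at 6.37 (4.88 to 8.18). These are well-studied transcripts, whereas the random lists were drawn from all non-coding genes. Epithelial-mesenchymal transition genes stood at 19 of 25 (76%, percentile 99.4), but at percentile 58.9 at a q-value under 1e-5, 74.8 with exonic and UTR peaks only, and 24% and percentile 24.3 for peaks with a fold of at least 4.

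Ribosomal protein and oxidative phosphorylation genes seldom held a peak by gene body. Of 78 cytosolic ribosomal protein genes, 20 were assigned a peak (25.6%, percentile 3.93, within the random range, but 0.815 at a q-value under 1e-5). By gene body 6 held one (7.69% against a random mean of 27.2%, percentile 0). They included RPL31, with a 3' UTR peak of fold 7.44 (6.29 to 8.75), RPL13, RPS29, RPL37 and RPL36. Peaks assigned to RPL27, RPLP1 and RPS26 lay in RUNDC1, KIF23 and IKZF4. Oxidative phosphorylation genes had 16 of 63 assigned (25.4%, percentile 0.61) and 10 by gene body (15.9%, percentile 0). Replication-dependent histone genes, whose transcripts lack poly(A) tails, had 4 of 50 assigned (8%, percentile 0.15) and 5 by gene body (H2BC5, H4C15, H1-1, H2BC4 and H3C6, percentile 11.7), or 2 by gene body at a q-value under 0.05 (percentile 2.24), so this call depended on the assignment and the threshold. Translation initiation and elongation factors lay within the random range, with 20 of 46 under either assignment (percentiles 38.9 and 43.5), EEF1D (15.1, 11.1 to 20.2) and EIF5B (9.53, 7.85 to 11.5) being the strongest. Stress granule and P-body genes had 17 of 33 assigned (percentile 43.1) and 24 by gene body (percentile 96.2, but 98.2 at a q-value under 0.05). LSM14A stood at 14.7 (10.5 to 20.2, on an alternative contig) and TNRC6B at 10.3 (7.48 to 13.8). The writer genes (7 of 11 assigned, percentile 81.5; 8 by gene body, percentile 92.7) lay within the random range, except by gene body at a q-value under 0.05 (percentile 98.5), and the erasers and readers (11 of 16 assigned, percentile 90.7) passed it by gene body (percentile 98.2), though not without intron peaks (95.9).

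**Figure D3:**
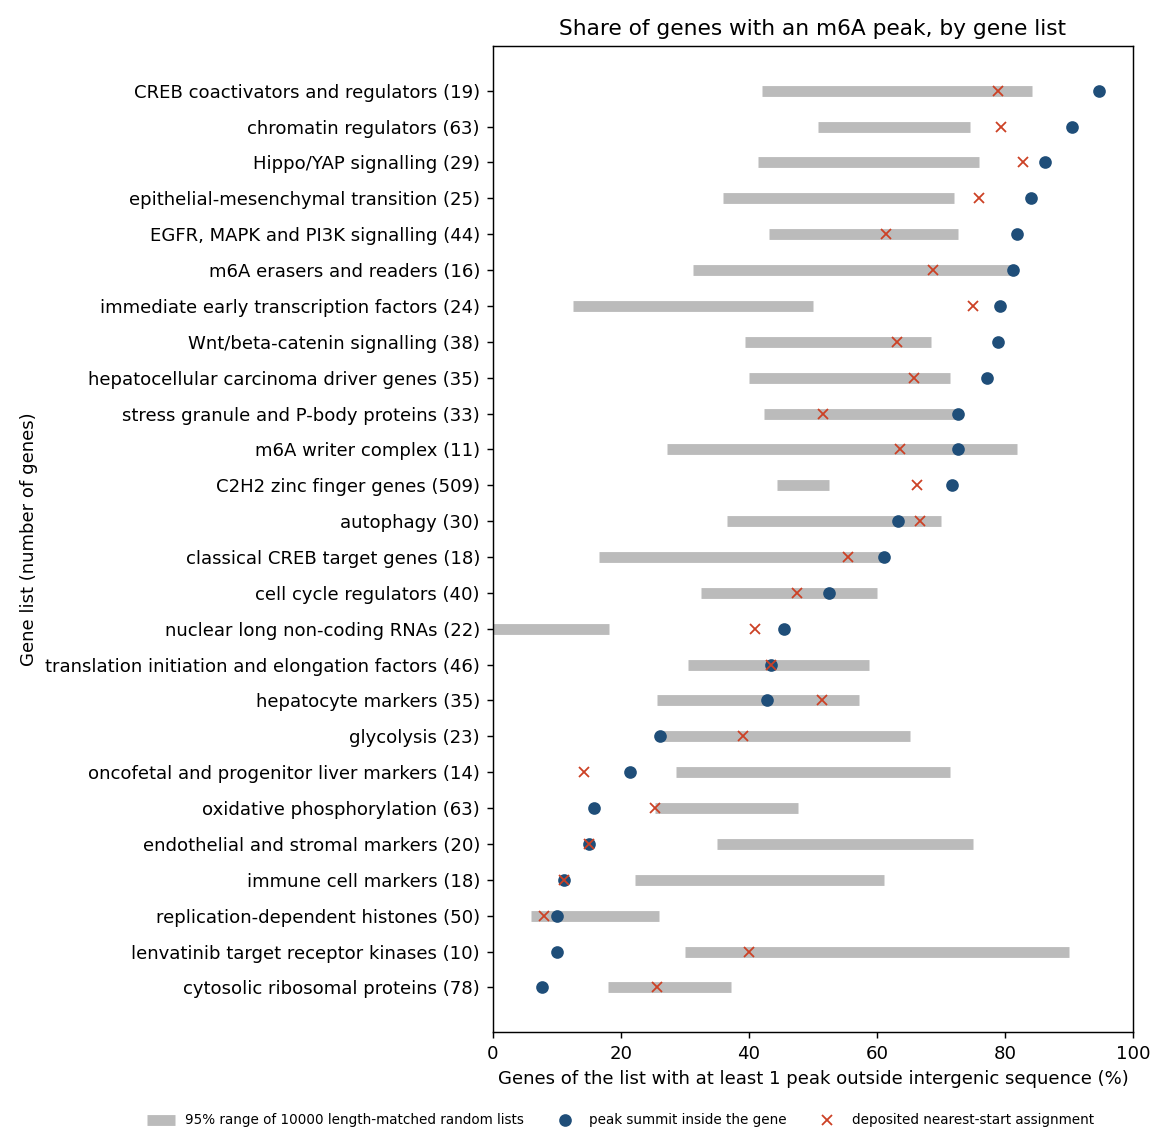
Percentage of the genes of each list with at least 1 peak outside intergenic sequence (horizontal axis), by gene body (circles) and by the deposited nearest-start assignment (crosses); grey bars are the central 95% of 10000 length-matched random lists by gene body, and the number of genes is in parentheses. Chromatin regulators (90.5%) lie above their random range and ribosomal protein genes (7.69%) below it by gene body.

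Strength of peaks separated fewer lists than their presence did. C2H2 zinc finger genes had a median highest fold of 5.46 (n = 337 genes, quartiles 3.89 to 7.56) against a random mean of 4.58, at percentile 100. Autophagy genes, at 2.97 (n = 20, quartiles 2.46 to 6.18, percentile 0.55), and epithelial-mesenchymal transition genes, at 3.25 (n = 19, 2.86 to 4.76, percentile 0.835), lay below their random lists. By gene body, autophagy genes had a median of 3.89 (percentile 14.9) and epithelial-mesenchymal transition genes 3.93 (percentile 4.79). Cell cycle regulators, at 3.16 (n = 21, percentile 1.4), and oxidative phosphorylation genes, at 2.86 (n = 10, percentile 2.03), lay below their random lists by gene body, against percentiles 87.9 and 8.77 by nearest start.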

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

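Of the 39801 peaks, 10267 had a q-value under 1e-5 and 13499 a fold of at least 4; these thresholds left 6144 and 7065 of the 12078 assigned genes. Merging peaks within 100 bp moved nothing, since the smallest gap was 151 bp, and so says nothing about stability. The share in exons and UTRs, 30.6%, was 57.0% at a q-value under 1e-5, 43.8% at a fold of at least 4 and 35.4% of peak bases. The ratio of median fold in 3' UTRs to that in introns, 1.42, was 1.34 in narrow peaks and reversed to 0.854 at a q-value under 1e-5. The caller requires a higher fold where fewer fragments lie, and intron peaks rest on fewer; whether this was the cause was not tested. By nearest start, 7 lists stood above their random range; there were 3 at a fold of at least 4, 4 with exonic and UTR peaks only and 11 without length matching. The 5 below it became 3 at a fold of at least 4. Epithelial-mesenchymal transition genes, 76%, reversed to 24% at that fold, below their random mean; the cause was not tested. For fold, 1 list stood above and 2 below; without matching on peak number 3 stood above, and with the median in place of the highest fold 1 stood below. Among alternatives chosen after seeing the data, a q-value under 0.05 left 19438 peaks, an exon and UTR share of 46.3% and a fold ratio of 1.02, and at least 10 RIP fragments gave 48.2% and 1.0. Assignment by gene body put 11 lists above the random range and 7 below it. The counts were 11 and 6 without intron peaks, and 12 and 7 at a q-value under 0.05. For fold, matching on input level put 3 lists above and 3 below. Those above were C2H2 zinc finger genes, hepatocyte markers (percentile 99.67) and chromatin regulators (99.2). Those below were autophagy, epithelial-mesenchymal transition and replication-dependent histone genes (0.82 for the histones, with 4 genes). No paired analysis was possible because there was 1 RIP and 1 input library, and no result came from a test. A second annotation of regions, stop codon density and the DRACH motif share were not run. Depth limits single peaks: a peak on 3 fragments, such as that of FLT1, has a fold interval of 1.12 to 5.32.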

Other observations

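The tests of few-fragment calls, of chance scatter and of gene length, and all values by gene body, were chosen after the results they bear on were seen. Glycolysis genes had 9 of 23 members assigned a peak (39.1%, percentile 22.9 of random lists), and 6 by gene body (26.1%, percentile 1.82; 2.59 without intron peaks and 5.75 at a q-value under 0.05). The lactate transporter gene SLC16A1 (3' UTR, fold 6.41, 5.28 to 7.71) and PFKFB3, an activator of glycolysis (6.26, 4.88 to 7.93), were strongest, and SLC2A2, HK1, HK2 and GPI had no peak by gene body. Cell cycle regulators lay within the random range, with 19 of 40 assigned (percentile 56.5) and 21 by gene body (percentile 81.1). FZR1, an activator of the anaphase-promoting complex, had a 3' UTR peak of fold 9.73 (7.53 to 12.4), E2F3 a promoter peak of 7.39 (5.63 to 9.53) and the phosphatase gene CDC25A a 3' UTR peak of 6.32 (4.31 to 8.99), while the cyclin genes CCND2, CCNE1, CCNE2 and CCNA2 had none. Autophagy genes had 20 of 30 assigned (66.7%, percentile 96.2) and 19 by gene body (percentile 87.6), with ATG14 (10.2, 7.13 to 14.1) and PIK3R4 (9.55, 7.55 to 11.9), partners in the lipid kinase complex that starts autophagosomes, the strongest.

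Within genes, intron peaks lay in intron 1 in 23.6% of 14913 cases, against 12.1% if each intron of a transcript were alike, and 22.6% at a q-value under 1e-5. Intron length was not taken into account here. Peaks in exons of coding transcripts lay in the last exon in 9.22% of 5323 cases, against 9.56% if exons were alike, but 3' UTR and promoter labels take precedence over the exon label. Of 25 epithelial-mesenchymal transition genes, 21 held a peak by gene body. The repressor genes ZEB2 (15.7, 13.1 to 18.8) and ZEB1 (9.90, 8.27 to 11.7) had strong 3' UTR peaks, and the 4 genes without a peak were FN1, TWIST1, CLDN1 and MMP2.

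Introns and intergenic sequence held 55.4% of all peaks. Calls on few fragments are not the whole of this, since 24.5% (interval 23.7 to 25.3) of peaks with a q-value under 1e-5 lay there. This was more than a limit of 10%, which was set after the results were seen. RNA present at these places in the input could contribute: the input level was above the genome-wide floor at 91.0% (89.8 to 92.0) of those strong intronic and intergenic peaks. Over all such peaks it was above the floor at 62.3%. Evenly spread input would give 56.4% if only a 1 kb window were counted. Recovered input levels such as 0.266 and 0.326 show that a wider window was also counted, so the even-spread value is higher. That value was not computed, so the test cannot decide on this explanation. The test also does not separate unspliced or unannotated RNA from genomic DNA. No biological explanation was tested, as both libraries are of 1 genotype.

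Intergenic peaks were bunched. Of 6934 on the main chromosomes, 439 (6.33%) lay in the 10 fullest of 1586 occupied windows of 1 Mb, where the median was 2 peaks. The fullest, on chromosome 8 from 89000000 to 89999999, held 58, and 0 of 1000 even placements over intergenic sequence reached this, the highest giving 16. Genes that the newer RefSeq table adds to the older annotation are not the main source. Of the 439, 16.6% (13.4 to 20.4) lay in a gene of the newer table, against 35.5% of other intergenic peaks. Transcripts absent from both annotations were not examined. Transcribed or multiplied DNA may contribute, as input was above the floor at 66.3% of these peaks and 52.0% of the others. The difference was 14.3 points (9.68 to 18.8), and 10 points had been set for it. This interval and that on the 16.6% treat peaks as independent. The 439 peaks came from only 10 windows, picked for their number of peaks, so both intervals are too narrow. The difference cannot decide on this explanation, which stays open.

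Ribosomal protein genes held few peaks by gene body, and short gene length may be part of this. By gene body the list's share stood at percentile 0 among random lists matched on gene span, whose central range was 17.9% to 37.2%. By nearest start, which also counts peaks lying in neighbouring genes, it stood at percentile 3.93. That percentile was 0.815 at a q-value under 1e-5, 15.2 at a q-value under 0.05 and 40.6 with exonic and UTR peaks only. These nearest-start settings disagree. By gene body the percentile was 0 without intron peaks and 0.055 at a q-value under 0.05. The gene-body share lay below its span-matched lists in each setting, so gene span alone does not account for it in these libraries. Exonic length was not matched and stays open as a cause. The median input level at the 6 peaks inside these genes was 8.27 (quartiles 2.14 to 12.9), against 1.0 in other protein-coding genes with an upper quartile of 4.0. With 6 peaks, and only genes that have one, too little RNA stays open too. Reads shared with the many processed pseudogenes of this family, and exon structure, were not tested.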
